A study of Populus trichocarpa with 18 samples.

How the data were processed

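Wild-type Populus trichocarpa (black cottonwood) trees were the source of all 18 libraries, per the labels. Stems were held bent for 21 days to form tension wood, the wood that broadleaf trees lay down on the upper side of a leaning stem. Normal wood came from the same kind of debarked stem segment; whether it came from unbent trees is not given in the sources used here. Cross-sections 16 µm thick were cut by laser into bands of differentiating xylem, the tissue in which newly formed wood cells build their walls. The bands called Region 1, Region 2 and Region 3 were kept, and their order relative to the cambium is not stated in the sources used here. About 1600000 µm2 of each region was pooled into 1 biological replicate, and each wood type had 3 biological replicates. Per the labels' protocols, libraries were made with a QIAGEN UPX kit that tags the ends of transcripts next to the poly(A) tail.

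The deposited values are whole-number counts per gene and library, in 1 table for normal wood and 1 for tension wood. Per the submitters' processing notes, UMI-tools, STAR and featureCounts were used, with no versions, settings or order. Whether each count is a read or a molecule after removal of duplicates is not given in the sources used here, so counting intervals and floors cover counting error only. The genome build is not named either; the gene identifiers end in the suffix of annotation version 4.1. The smallest row sum was 1 in both tables, so genes without a count in any library of a table are absent from it. The normal table lists 6763 genes and that of tension wood lists 8878; 4347 genes are in both and 11294 in either. Every column matched a labelled sample, and 0 columns were left unused.

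The depth was low and differed between the woods. Totals ran from 6254 to 20080 counts in normal libraries and from 8982 to 89358 in tension libraries. A total of 6254 puts the floor of 3 counts at 480 CPM (a count scaled to the total of all counts of its library), against 33.6 CPM at a total of 89358. CPM printed for single genes are instead relative to the counts of the genes tested in that comparison, scaled by TMM, so they are higher, differ between comparisons for the same library and are not to be set against these floors. No pair of libraries held identical values, and no pair within a wood agreed within sampling noise, so none was treated as 1 library deposited again. This check was against counting noise alone, and replicates of a group were about as far apart as libraries of different groups (median chi-square over degrees of freedom 2.63 against 2.64 in normal and 2.21 against 2.15 in tension wood).

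The main test was the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter at a minimum count of 10, and Benjamini-Hochberg adjusted p under 0.05. Tension was compared with normal wood within each region over 6 libraries, and again on counts summed over the 3 regions of each biological replicate, using genes listed in both tables and no block. Regions were compared within each wood over its 9 libraries with the biological replicate as a block, because each label ties 3 regions to 1 biological replicate. In the data this tie was weak: deviations from the group means of same-numbered regions had a median correlation across genes of 0.018 in normal and 0.012 in tension wood. The difference between woods in the Region 3 against Region 1 change was fitted over all 18 libraries with 6 blocks. These designs, the rule for named genes and the alternatives other than scaling by library totals and thinning were fixed before the data were examined. By that rule, the largest changes with no overlap between groups (for regions, the same sign in each of the 3 replicates) were to be named where a description exists, along with members of fixed gene lists.

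The reference gene table for assembly P.trichocarpa_v4.1 matched 0 of the 11294 identifiers, so the data pair no identifier with a gene name. Identifiers without a description are counted, and at most 2 that rose and 2 that fell are printed per comparison. The fixed lists therefore rest on 67 poplar identifiers recalled from published gene models and written down before the data were examined. Their membership was not checked against any annotation, and 56 of them (83.6%) occur in either table. The 7 lists with identifiers were secondary wall cellulose synthases, primary wall cellulose synthases, cellulose synthesis accessory proteins, fasciclin-like arabinogalactan proteins, monolignol biosynthesis, xylan biosynthesis and secondary wall transcription factors. The other 18 of 25 lists, including all markers of tissues outside the xylem, needed descriptions and were not analysed here. Near-identical copies of a gene can share tags, and how the counting split these is not given in the sources used here.

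Lists with at least 5 tested members were tested with camera of limma 3.58.1, which compares a list with all other genes, at a preset correlation between genes of 0.01 and again with an estimated correlation. The fry test, which asks whether the members move on balance one way, was run beside it. Shares of a library's counts were compared by exact two-sided permutation tests, in which 3 libraries against 3 cannot give a p below 0.1. Where a group held 0 counts, folds were computed against a floor of 3 counts over the group, on the TMM-scaled totals of the tested genes, and are lower bounds under that scaling only; bounds on all counts of the libraries are given beside them. Where it held 1 to 3 counts, the ratio of summed counts, over the same TMM-scaled totals, is given with its exact 95% counting interval.

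Alternatives were the size factors of DESeq2 1.42.0 in the same test, the DESeq2 Wald test, no low-count filter, a minimum count of 3, the replicate number as a block or its removal, genes of either table, all 18 libraries in 1 fit, and each replicate left out in turn. Scaling by library totals and thinning all libraries of a fit to its smallest total were added after the data were seen. The code was tested on simulated counts with 100 genes changed 2-fold and 100 changed 4-fold. For tension against normal wood in Region 1 (973 genes tested), 28.6% of the tested 2-fold and 89.9% of the tested 4-fold changes were recovered. For Region 3 against Region 1 the shares were 23.4% and 96.7% in normal wood (397 genes tested) and 16% and 84.7% in tension wood (1189 genes tested). For the interaction (416 genes tested) they were 9.09% and 44.4%. For the tests between the woods and the interaction, the simulated woods shared 1 mean profile apart from the changed genes. The real profiles of the woods were nearly unrelated (median Spearman correlation 0.097). These shares therefore do not cover scaling across dissimilar profiles. Figures were drawn with matplotlib 3.10.9.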

Results

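Gene counts were collected from 3 laser-captured bands of differentiating xylem, named Region 1 to 3, in normal and in tension wood of Populus trichocarpa stems. Each of the 6 groups held 3 biological replicates. The mean total per library in normal wood was 12074 ± 1242 counts in Region 1, 12120 ± 6931 in Region 2 and 8048 ± 1797 in Region 3 (SD, n = 3). In tension wood it was 81032 ± 13704, 44996 ± 9927 and 16085 ± 10041 counts (SD, n = 3). Between 1728 and 3197 genes had at least 1 count in a normal library, and between 2658 and 5583 in a tension library. The 10 most abundant genes took 6.06% to 7.13% of the counts of normal libraries and 9.05% to 9.89% of those of tension libraries.

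**Figure D1:**
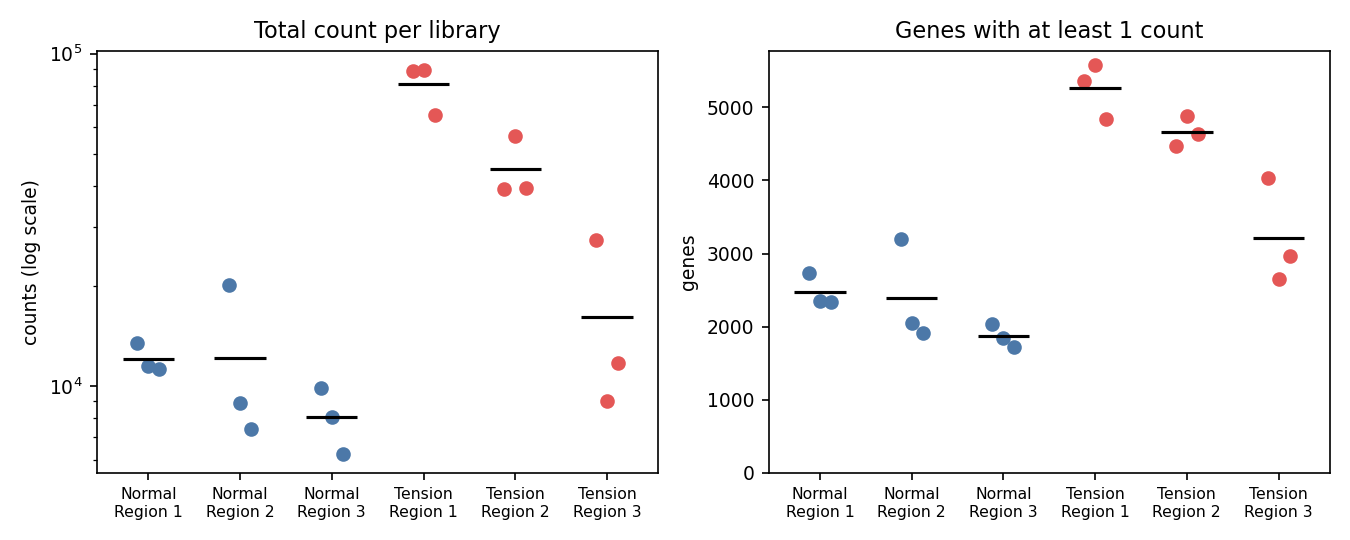
Total counts (left, log scale) and genes with at least 1 count (right) per library, by wood type and region; points are the 3 libraries of a group and bars their mean. Tension libraries of Region 1 held between 65215 and 89358 counts, whereas no normal library exceeded 20080.

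The 18 profiles fell into 2 blocks by wood type. Across the 4347 genes listed in both tables, the Spearman correlation had a median of 0.603 between normal libraries (range 0.581 to 0.631) and 0.840 between tension libraries (range 0.658 to 0.900). Between a normal and a tension library it ranged from 0.057 to 0.146, with a median of 0.097. These values are across genes, which are not independent replicates. Over the 481 genes with at least 200 counts in all libraries together, the Pearson correlation of log2(CPM + 50) had a median of -0.22 between the woods (range -0.26 to -0.17), 0.829 within normal and 0.912 within tension wood. Genes were chosen here by their sum over both woods, and the effect of that choice on the value between the woods was not measured. With all libraries thinned to 5733 counts in these genes, the medians were 0.589 within normal, 0.594 within tension and 0.098 between the woods.

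**Figure D2:**
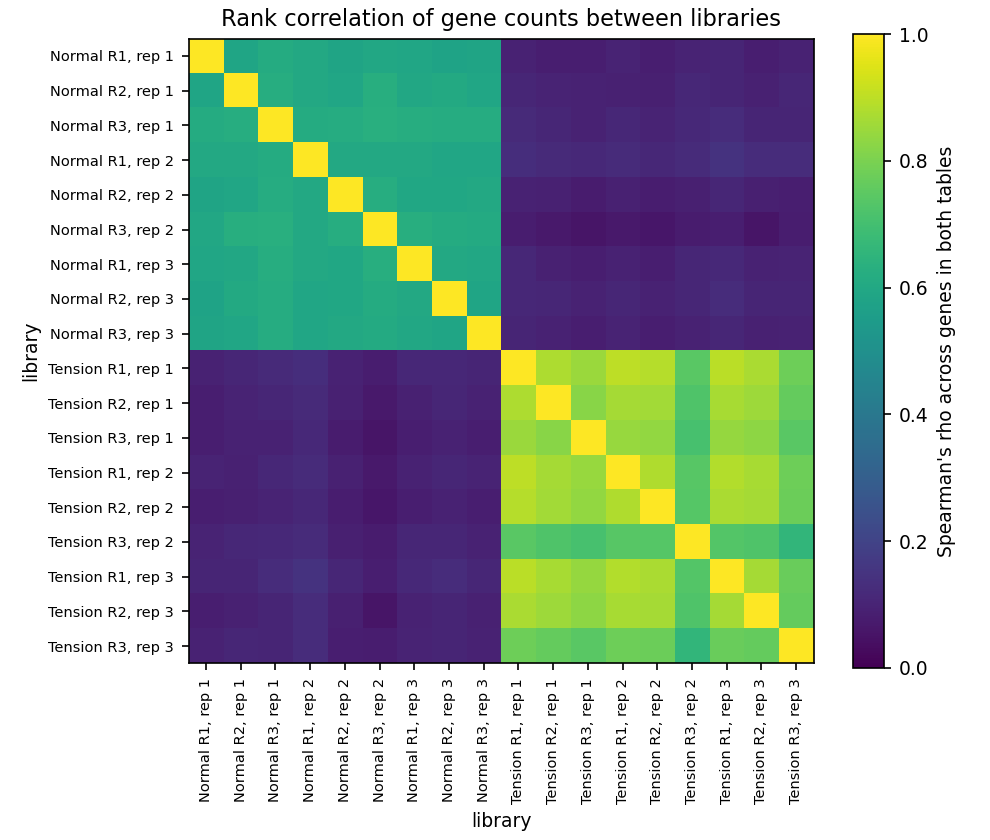
Spearman correlation across the 4347 genes of both tables for every pair of the 18 libraries, ordered by wood type and replicate; R1 to R3 are Regions 1 to 3. Pairs within a wood reach at least 0.581, and pairs between the woods stay at or below 0.146.

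The comparison of tension with normal wood asks how xylem that develops under mechanical stress differs from xylem of normal wood. Each table holds 1 wood and no preparation is named, so differences between the woods cannot be told apart from separate preparation or sequencing. Whether both tables were aligned and counted with the same settings is not given either, so that cannot be told apart from the wood. Gene groups below are lists of poplar identifiers recalled before the data were examined, so each count is of list members, not of annotated genes. In Region 1, members of the lists for the fibre wall polymers were higher in tension wood. All 5 secondary wall cellulose synthases, the enzymes that spin cellulose into thickened walls, rose, with a median log2 fold change of 3.15. All 7 tested fasciclin-like arabinogalactan proteins, cell surface glycoproteins abundant in developing xylem, rose as well, with a median of 3.97. In the monolignol list, which holds enzymes of lignin precursor synthesis, 14 of 15 tested members rose (median 2.29), and in the xylan list, for the main hemicellulose of the wood wall, 5 of 6 rose (median 3.31). Both tested accessory proteins of cellulose synthesis rose, with log2 fold changes of 2.82 and 5.32.

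These medians stand against a median of 1.37 over all 1037 genes tested in Region 1. Relative to that median, the lists lay higher by 1.78 (cellulose synthases), 2.61 (fasciclin-like proteins), 0.92 (monolignols) and 1.94 (xylan). By the edgeR test, 913 of the 1037 genes differed, 544 higher and 369 lower in tension wood. Adjusted over the list alone, the counts of members that rose were equal in these lists; under scaling by library totals 9 of 15 monolignol genes rose and the remaining xylan member fell. The camera test placed the fasciclin-like and monolignol lists above other genes (adjusted p = 0.013 for each), and with an estimated correlation neither passed (adjusted p = 0.185 for each). The cellulose synthase and xylan lists did not pass it (adjusted p = 0.053 and 0.119, or 0.185 for each with an estimated correlation).

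The fasciclin-like list took 3.63% ± 0.33 of tension counts and 0.680% ± 0.120 of normal counts in Region 1 (SD, n = 3), and the monolignol list 3.38% ± 0.12 and 1.57% ± 0.23. Secondary wall cellulose synthases took 1.13% ± 0.073 against 0.239% ± 0.025, the xylan list 0.406% ± 0.023 against 0.119% ± 0.039, and accessory proteins 0.151% ± 0.030 against 0.031% ± 0.034 (0.012% in normal wood without replicate 2). Every tension library lay above every normal library for these 5 lists (exact permutation p = 0.1 for each, the smallest possible, and adjusted p = 0.117 over 21 tests). The secondary wall transcription factor list had 1 tested member, with a log2 fold change of -1.11 that was not called (adjusted p = 0.051), although scaling by library totals called it lower. Potri.004G143200.v4.1 was at least 27.1-fold higher in tension wood, at 2295 ± 647 CPM against 0 counts (SD, n = 3; adjusted p = 2.0e-11), and Potri.016G010200.v4.1 at least 23.4-fold higher (adjusted p = 8.8e-11); on all counts of the libraries, without TMM, the bounds were 12.5-fold and 10.8-fold. Potri.015G073000.v4.1 was at least 63.5-fold lower, at 0 counts against 1730 ± 359 CPM (SD, n = 3; adjusted p = 2.8e-14), and Potri.008G042700.v4.1 at least 50.5-fold lower (adjusted p = 7.3e-13), or 138-fold and 109-fold on all counts.

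The count of calls in Region 1 moved with the number of genes that could be tested: it was 405, 413 and 411 without tension replicate 1, 2 and 3, 1427, 1434 and 1413 without normal replicate 1, 2 and 3, and 274 (111 higher, 40.5%, against 59.6% in the main test) with all libraries thinned to the smallest total. The monolignol list missed the camera threshold without normal replicate 2 (adjusted p = 0.064), the cellulose synthase list passed it without normal replicate 1 (adjusted p = 0.041), and a minimum count of 3 ended the fasciclin-like and monolignol calls (adjusted p = 0.090 and 0.231).

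**Figure D3:**
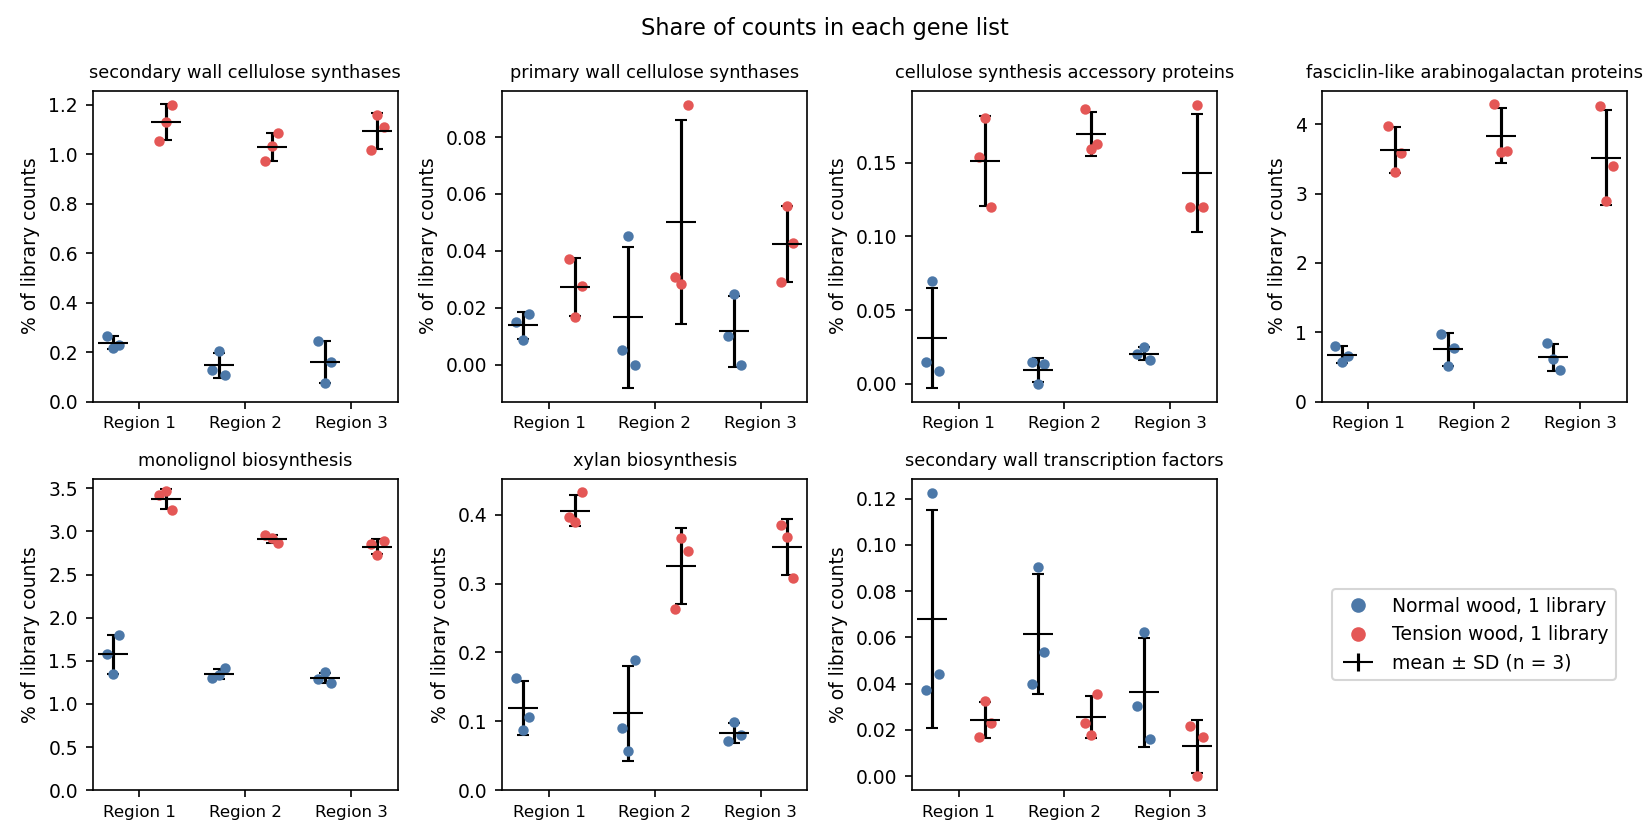
Percent of each library's counts (vertical axes, different scales) in the 7 recalled gene lists, by region, for normal and tension wood; points are libraries, bars the mean and SD of 3. Group means of the fasciclin-like list lie between 0.639% and 0.753% in normal wood and between 3.52% and 3.83% in tension wood.

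In Region 2, list members that passed the test were all higher in tension wood. All 4 tested secondary wall cellulose synthases rose (median log2 fold change 3.77), as did all 7 fasciclin-like proteins (median 3.53, also with the 1 member at 0 counts in normal wood placed at its bound). In the monolignol list 13 of 15 rose (median 2.41). Both tested xylan members rose (2.98 and 3.58), and so did both accessory proteins (4.53 and 4.62). The median of all 798 genes tested was 0.43, and the lists lay above it by 3.34, 3.10, 1.99, 2.85 and 4.15 in that order.

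By the edgeR test, 704 of these 798 genes differed in Region 2, 365 higher and 339 lower. Shares of counts in Region 2 were 3.83% ± 0.40 in tension against 0.753% ± 0.233 in normal wood for the fasciclin-like list, 2.91% ± 0.043 against 1.35% ± 0.059 for monolignols, 1.03% ± 0.057 against 0.147% ± 0.050 for secondary wall cellulose synthases, and 0.326% ± 0.055 against 0.112% ± 0.069 for xylan (SD, n = 3; 0.073% in normal wood without replicate 3). The camera test placed the fasciclin-like and monolignol lists higher than other genes (adjusted p = 0.0086 for each), and neither passed with an estimated correlation (adjusted p = 0.213 and 0.180). Potri.003G143200.v4.1 was at least 28.2-fold higher, at 3025 ± 344 CPM against 0 counts (SD, n = 3; adjusted p = 1.8e-09), and Potri.013G151300.v4.1 at least 21.6-fold higher (adjusted p = 1.5e-08), with bounds of 16.4-fold and 12.6-fold on all counts. Potri.003G070600.v4.1 was at least 41.0-fold lower, at 0 counts against 2043 ± 665 CPM (SD, n = 3; adjusted p = 3.3e-09), and Potri.016G138600.v4.1 at least 38.9-fold lower (adjusted p = 5.7e-09), or 74.3-fold and 68.7-fold on all counts. By its log2 fold change of 8.09, Potri.013G151300.v4.1 is the fasciclin-like member at 0 counts in normal wood. It is therefore no result apart from that list. Thinned to the smallest total, 151 of 164 genes were called in Region 2, 41.7% of them higher against 51.8% in the main test. A minimum count of 3 gave 71.1% higher and ended both camera calls (adjusted p = 0.054 and 0.070), and thinning ended that of the monolignol list (adjusted p = 0.081).

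In Region 3, where tension libraries were shallowest, both tested secondary wall cellulose synthases rose in tension wood (3.95 and 4.41). Of the fasciclin-like list 5 of 6 tested members rose (median 2.78), and of the monolignol list 8 of 10 (median 1.95). The only tested xylan member rose (3.11). All genes tested had a median of -1.39, and the lists lay above it by 5.57, 4.17, 3.33 and 4.49. The genes tested differed between Regions 1 to 3 (1037, 798 and 217), as did their median (1.37, 0.43 and -1.39). Distances from it therefore cannot be compared between regions. Ratios of shares, tension over normal, were 2.15, 2.16 and 2.17 in Regions 1 to 3 for monolignols. For the fasciclin-like list they were 5.33, 5.09 and 5.51. In Regions 1 to 3 they were 4.73, 7.005 and 6.87 for secondary wall cellulose synthases, and 3.42, 2.92 and 4.23 for xylan. Region 2 thus had the highest ratio for cellulose synthases and the lowest for xylan, so neither list moved steadily from Region 1 to Region 3. Single normal libraries of Region 3 held as few as 6 counts of the cellulose synthases and 5 of the xylan list. The edgeR test called 195 of 217 genes, 81 higher and 114 lower in tension wood.

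The fasciclin-like list took 3.52% ± 0.69 of tension and 0.639% ± 0.191 of normal counts in Region 3, the monolignol list 2.82% ± 0.086 and 1.30% ± 0.061, and secondary wall cellulose synthases 1.09% ± 0.073 and 0.159% ± 0.085 (SD, n = 3). Camera placed the fasciclin-like and monolignol lists higher than other genes (adjusted p = 0.0071 for each); with an estimated correlation the values were adjusted p = 0.228 and 0.094. Potri.009G152800.v4.1 was at least 14.6-fold higher, at 4600 ± 651 CPM against 0 counts (SD, n = 3; adjusted p = 9.0e-06; at least 10.96-fold on all counts). Potri.002G078600.v4.1 had 107 counts against 1, a ratio of 72.2 with an exact 95% counting interval from 12.7 to 2879 (adjusted p = 2.9e-06), and on all counts a ratio of 53.5 (interval 9.41 to 2134). Potri.005G051200.v4.1 was at least 26.9-fold lower (adjusted p = 3.4e-06) and Potri.018G108500.v4.1 at least 25.3-fold lower (adjusted p = 6.8e-06), or 36.2-fold and 34.0-fold on all counts. Fitting all 18 libraries together called 503 of 573 genes in Region 3, and thinning called 98 of 109.

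The 3 regional comparisons used different libraries of the same biological replicates. Of the 217 genes tested in all 3 regions, 80 were called higher in tension wood in all 3 and 102 lower in all 3. Lists independent of each other would have shared 13.2 and 26.4. All 3 comparisons set the same woods against each other, so independence was not to be expected and the excess over it lends no support. No gene was called in opposite directions in different regions. How much of the overlap comes from the shared replicates was not measured.

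With the 3 regions summed per biological replicate, 1746 of 1932 genes differed, 1083 higher and 663 lower in tension wood. The sums weight regions by depth, with mean totals of 81032, 44996 and 16085 counts in Regions 1 to 3 of tension wood. In normal wood the means were 12074, 12120 and 8048, so the sums mix the regions in different shares in each wood. All 5 secondary wall cellulose synthases rose (median 2.83), as did 6 of 7 fasciclin-like proteins (median 2.65) and both accessory proteins (2.25 and 4.41). Of the xylan list 5 of 6 rose and 1 fell (median 2.55), and of the monolignol list 11 of 20 rose, 1 fell and 8 did not pass (median 1.29); under library totals and under the size factors of DESeq2, 15 and 16 rose. The single tested secondary wall transcription factor fell by 2.10 on the log2 scale. All genes tested had a median of 1.76, so the monolignol median differed from it by -0.47, although camera placed that list on the higher side without passing (adjusted p = 0.102).

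In the summed data camera passed for the fasciclin-like list (adjusted p = 0.035, and 0.439 with an estimated correlation) but not for cellulose synthases (adjusted p = 0.102) or xylan (adjusted p = 0.240). Potri.008G156200.v4.1 had 268 counts in tension and 1 in normal wood, a ratio of 60.0 (exact 95% counting interval 10.7 to 2378; adjusted p = 3.7e-12), and Potri.013G055100.v4.1 had 259 against 1 (interval of the ratio 10.3 to 2299; adjusted p = 1.2e-11). Potri.003G070600.v4.1 had 1 count in tension and 168 in normal wood, a ratio of normal to tension of 751 (133 to 29819; adjusted p = 1.3e-40), and Potri.002G141500.v4.1 a ratio of 581 (102 to 23113; adjusted p = 3.2e-36). Thinned to the smallest total, 694 of 754 genes were called, 41.2% of them higher against 62.0% in the main test. The fasciclin-like call ended without normal replicate 2 (adjusted p = 0.061) and with genes of either table (adjusted p = 0.212), while leaving out tension replicate 1, 2 or 3 brought the monolignol list past the threshold (adjusted p = 0.028, 0.032 and 0.015) and likewise the cellulose synthases (adjusted p = 0.033, 0.032 and 0.034).

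**Figure D4:**
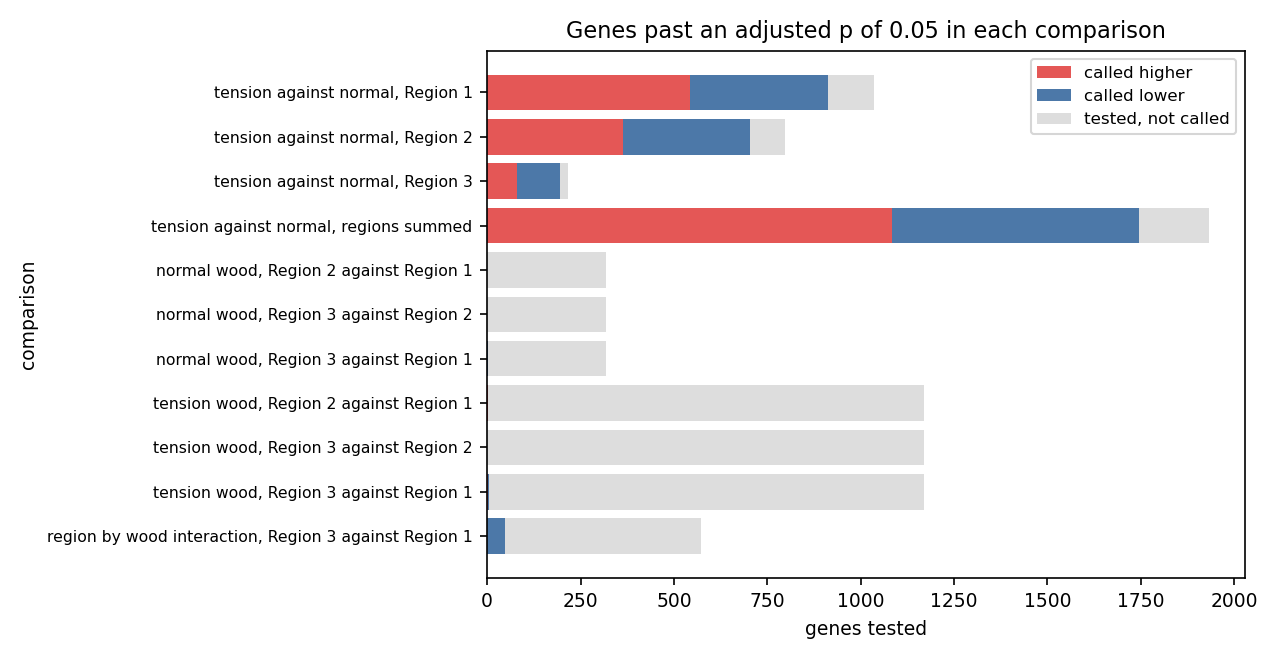
Genes tested per comparison (bar length) and those past a Benjamini-Hochberg adjusted p of 0.05 in the edgeR test, split into higher and lower in the first-named condition. Between 88.0% and 90.4% of tested genes were called between the woods, and at most 4 genes between regions of a wood.

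The comparisons of regions within a wood ask how expression differs between bands of the developing xylem. In normal wood, 1 gene was called in the 3 comparisons of regions. This was Potri.016G104300.v4.1, which was lower in Region 3 (7527 ± 885 CPM) than in Region 1 (14863 ± 4199 CPM; SD, n = 3), with a log2 fold change of -0.94 (SE 0.24, adjusted p = 0.043, the same sign in 3 of 3 replicates). Few list members reached the filter, namely 1 secondary wall cellulose synthase, 2 fasciclin-like proteins and 3 monolignol genes, and none was called over all genes.

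In normal wood the tested cellulose synthase had log2 values of -1.23 in Region 2 and -1.02 in Region 3 against Region 1. Neither was called over all genes by edgeR (adjusted p = 0.830 and 0.537). Over the list alone, which held this 1 tested member and so needed no adjustment, its edgeR p was under 0.05 for Region 2 against Region 1. That unadjusted level was reached by 13 of the 318 genes tested, so it does not set this gene apart. Of the 2 fasciclin-like members 1 was lower in Region 3 than in Region 1 when adjusted over the list alone. The 3 monolignol genes had medians of 0.05, -0.19 and -0.02 for Region 2 against 1, 3 against 2 and 3 against 1. Of 318 genes tested, edgeR and DESeq2 both called 0 for Region 2 against Region 1 (13 with an unadjusted p under 0.05 in edgeR) and 0 for Region 3 against Region 2 (21 with an unadjusted p under 0.05). The call of Potri.016G104300.v4.1 did not pass without replicate 2 (adjusted p = 0.594), without replicate 3 (adjusted p = 0.483) or without the replicate block (adjusted p = 0.357), and DESeq2 called 0 genes.

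Of the genes tested in tension wood, 2 were called between Region 2 and Region 1, and 2 of the 10 splits of the libraries, the real one included, gave as many calls. Potri.010G012100.v4.1 rose from 13955 ± 258 to 20215 ± 4021 CPM (SD, n = 3; log2 fold change 0.52, SE 0.089, adjusted p = 0.00054), and Potri.015G129400.v4.1 fell from 3869 ± 1299 to 1999 ± 402 CPM (log2 fold change -0.93, SE 0.19, adjusted p = 0.0064), each in 3 of 3 replicates. As groups against all other genes, camera placed monolignol biosynthesis (median -0.20, 18 members, adjusted p = 0.0035), xylan biosynthesis (median -0.28, 7 members, adjusted p = 0.023) and secondary wall cellulose synthases (median -0.16, 5 members, adjusted p = 0.032) lower in Region 2. It placed fasciclin-like proteins higher (median 0.17, 7 members, adjusted p = 0.0042). With an estimated correlation none of these 4 lists passed (adjusted p = 0.090 for monolignols, 0.177 for xylan, and 0.124 for the cellulose synthases and the fasciclin-like list).

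No single member of these lists was called over all genes in tension wood Region 2 against Region 1, and 1 monolignol gene was lower when adjusted over the list alone. The edgeR test called 2 of 1171 genes. DESeq2 called 0, and the count was 1, 0 and 1 without replicate 1, 2 and 3; Potri.010G012100.v4.1 did not pass without replicate 1, 2 or 3 (adjusted p = 0.105, 0.900 and 0.979), nor Potri.015G129400.v4.1 without replicate 1 or 2 (adjusted p = 0.155 and 0.900). Camera missed the threshold for cellulose synthases without replicate 1 or 2 (adjusted p = 0.096 and 0.129), for fasciclin-like proteins without replicate 1 or 3 (adjusted p = 0.096 and 0.055) and for xylan without replicate 1 (adjusted p = 0.188), and without a low-count filter the fasciclin-like list lay on the lower side of other genes (median 0.028, adjusted p = 0.175).

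Between Region 3 and Region 1 of tension wood, 2 genes rose and 2 fell. Potri.010G012100.v4.1 rose from 13955 ± 258 to 22929 ± 164 CPM (SD, n = 3; log2 fold change 0.72, SE 0.092, adjusted p = 6.8e-07) and Potri.005G248100.v4.1 from 4423 ± 240 to 7796 ± 2848 CPM (0.76, SE 0.17, adjusted p = 0.023). Potri.015G129400.v4.1 fell to 2031 ± 486 CPM (-0.94, SE 0.22, adjusted p = 0.031) and Potri.013G157900.v4.1 from 5837 ± 795 to 3537 ± 415 CPM (-0.71, SE 0.17, adjusted p = 0.031). All 4 had the same sign in 3 of 3 replicates. Potri.013G157900.v4.1 is also the 1 called member of the monolignol list, since Potri.015G129400.v4.1 lies below the lowest value of that list (-0.86). The monolignol list was lower as a group (median -0.11 over 18 members, 1 of them called and 3 called over the list alone; camera adjusted p = 0.020, and adjusted p = 0.154 with an estimated correlation).

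Other lists did not pass for tension wood Region 3 against Region 1: cellulose synthases had a median of -0.12 (adjusted p = 0.548), fasciclin-like proteins of 0.07 (adjusted p = 0.548) and xylan of -0.25 (adjusted p = 0.556). These values share the Region 1 libraries with the comparison of Region 2 with Region 1, so their directions are not independent of it. DESeq2 called only Potri.010G012100.v4.1, with an adjusted p of 0.037. Without replicate 2 the edgeR test called 0 genes and the monolignol list missed the threshold (adjusted p = 0.097), and without replicate 1 it called 2, with Potri.010G012100.v4.1 at an adjusted p of 0.095.

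Between Region 3 and Region 2 of tension wood no gene passed the edgeR test or DESeq2 (0 of 1171; 56 with an unadjusted p under 0.05 in edgeR). Medians were 0.04 for secondary wall cellulose synthases, -0.12 for fasciclin-like proteins, -0.02 for monolignols and 0.25 for xylan, and camera called none (smallest adjusted p = 0.488). Without replicate 1 the edgeR test called 1 gene and camera placed the fasciclin-like list lower (adjusted p = 0.0030). Thinning also placed that list lower (adjusted p = 0.0069).

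The interaction asks whether the change from Region 1 to Region 3 differed between the woods. By the edgeR test it differed for 49 of 573 genes, all with a lower value in tension relative to normal wood, while the median of all tested genes was itself -1.34. Among the lists, 3 of 11 monolignol genes and 1 of 7 fasciclin-like proteins were among the calls. Camera placed neither list apart from other genes (adjusted p = 0.148 for each). Potri.004G172000.v4.1 went from 4424 ± 675 to 6914 ± 4113 CPM in normal wood and from 484 ± 204 to 54.5 ± 94.4 CPM in tension wood (SD, n = 3), a log2 difference of -3.73 (SE 1.10, adjusted p = 0.026). That value rests on 1 count in tension Region 3 against 25 in Region 1 (ratio 0.086, exact 95% counting interval 0.0021 to 0.527), and with all libraries thinned to the smallest total it was 1.30 (adjusted p = 0.960). Potri.009G044600.v4.1 went from 93.8 ± 6.8 to 348 ± 176 CPM in normal wood and from 3990 ± 127 to 1390 ± 496 CPM in tension wood, a log2 difference of -3.16 (SE 1.09, adjusted p = 0.045). Its normal counts were 7 in Region 3 and 3 in Region 1, a ratio of 3.44 with an interval from 0.785 to 20.6.

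Under scaling by library totals the median of all genes was -0.09 and 3 genes were called, all higher, and with the size factors of DESeq2 it was -0.24 with 1 call, also higher; none of the 49 genes was among them, and the DESeq2 test called 0. The count was 5, 4 and 3, all higher, without normal replicate 1, 2 and 3, and 63, 7 and 4, all lower, without tension replicate 1, 2 and 3. Of the 63 calls without tension replicate 1, 41 were among the 49, and camera then placed the fasciclin-like list lower (adjusted p = 0.039).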

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

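All tests in this part were chosen after the result was seen, except the interaction itself, DESeq2 and its size factors, which were planned. The change from Region 1 to Region 3 differed between the woods for 49 of 573 genes, among them Potri.009G044600.v4.1 (log2 difference -3.16) and Potri.004G172000.v4.1 (log2 difference -3.73, resting on 1 count in tension Region 3, and 1.30 with all libraries thinned to the smallest total); the difference was tested directly. All 49 lay on the lower side, and a candidate cause is the set of scaling factors fitted across dissimilar profiles, which ran from 0.444 to 1.54. Under median-of-ratios factors and under library totals, 0 of the 49 genes were called; their median log2 difference went from -2.09 ± 0.58 (SD over the genes) to -0.96 ± 0.61 and -0.82 ± 0.61 at a median SE of 0.70, 0.66 and 0.65, so the calls ended because the estimates shrank. The scaling fits as a cause of the shift that all genes shared (median -1.34, then -0.24 and -0.09), whereas the 49 lay 0.76, 0.72 and 0.72 below that median, with 48 and 45 still negative, which their choice as lower could give by itself, so a difference between the woods in the regional change stays open. The 10 splits of the biological replicates are too few for a share under 0.05. The real split gave 49 calls and the highest other split 0. Every other split put replicates of both woods in each group, so any difference between the woods entered its spread, and the 0 lends no support.

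Some counts lay in genes that the main comparisons between the woods did not use, because only 1 of the tables lists them. These genes held 7.46% of all normal counts (2416 genes, 143 of them with at least 10 counts) and 13.2% of all tension counts (4531 genes, 1121 with at least 10 counts). No control level exists for these shares, so the shares themselves show only how much was left out. With genes of either table let in, the summed comparison called 1967 genes, of which 1708 were among the main 1746. Regions 1 to 3 then gave 971, 707 and 189 calls, with 910, 664 and 189 among their main calls. How many of the added calls lie in genes of 1 table alone was not counted.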

How the results depend on the processing

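Scaling by library totals and thinning to the smallest total were chosen after the data were seen; the others were planned. Between the woods, no called gene changed direction in any alternative that also called it, and counts under both other scalings, DESeq2 and genes of either table stayed within 1.5 times the main count. The main counts of 913, 704, 195 and 1746 (Regions 1 to 3 and summed) followed the number of genes tested. Without a low-count filter the regions gave 2363, 1735 and 1091 calls, at a minimum count of 3 they gave 1787, 1681 and 620, and thinned they gave 274, 151 and 98, with 694 for the sums. Fitting all 18 libraries together gave 488 in Region 1 and 503 in Region 3. Leaving out 1 replicate gave 405 to 1434, 605 to 1053, 207 to 274 and 1320 to 1945. Library totals put the median log2 fold change of all genes at 0.54, -0.02 and -1.48 in Regions 1 to 3, against 1.37, 0.43 and -1.39 with TMM.

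Normal and tension libraries share replicate numbers but no stated tree or day, so by the planned design they were not treated as pairs. Same-numbered libraries of 1 region had correlations of deviations between -0.047 and 0.060, and 6 of 18 libraries correlated best with their own number. Regions that the labels tie to 1 biological replicate had medians of only 0.018 in normal and 0.012 in tension wood. These correlations therefore cannot show whether the numbers mark pairs. The replicate block gave 893, 686, 193 and 1692 calls. Between regions, removing the block left 0, 0 and 0 calls in normal wood (Region 2 against 1, 3 against 2, 3 against 1), 2, 0 and 5 in tension wood and 47 in the interaction; apart from Potri.016G104300.v4.1 in normal wood (adjusted p = 0.357) and Potri.013G157900.v4.1 in tension wood (adjusted p = 0.053), it ended no call of a named gene, and neither the block nor its removal ended a list call.

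The single call between Region 3 and Region 1 of normal wood became 0 with DESeq2's size factors, DESeq2, no low-count filter, a minimum count of 3, thinning or no replicate block, and 0 to 1 with a replicate left out. In tension wood, Region 2 against Region 1 gave 0 with DESeq2, 1 thinned and 0 to 1 with a replicate left out; Region 3 against Region 2 gave 0 to 1; Region 3 against Region 1 gave 1 with DESeq2, 8 without a filter and 0 to 5 with a replicate left out. The 49 interaction calls became 1 with DESeq2's size factors, 0 with DESeq2, 7 without a filter, 3 at a minimum count of 3, 3 with library totals, 0 thinned and 3 to 63 with a replicate left out; beyond the scaling, the cause was not tested. Without a filter the fasciclin-like list moved to the other side in tension wood Region 2 against 1 (median 0.028) and Region 3 against 1 (median -0.21), and thinning turned Potri.004G172000.v4.1 in the interaction (log2 difference 1.30); the cause was not tested. The fry test passed for every list tested between the woods (largest adjusted p = 0.0026) and for both lists in the interaction (adjusted p = 0.025 and 0.011), and in tension wood it passed for 3 of 4 lists in Region 2 against 1, missing for xylan (adjusted p = 0.091), and for none of the 4 in Region 3 against 2 (adjusted p = 0.195 to 0.887) or Region 3 against 1 (adjusted p = 0.116 to 0.903). Fry does not compare a list with other genes, and 88.0% to 90.4% of all tested genes were called between the woods. In the interaction the median of all genes was itself -1.34 with TMM, and camera gave adjusted p = 0.148 for each list. These fry results between the woods and in the interaction therefore do not set the lists apart from other genes. Lists chosen by gene description could not be run, because no description matched. Floors of 33.6 to 480 CPM per library leave genes of low expression undetectable.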

Other observations

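The gene lists and the edgeR tests were planned. All other tests in this part were chosen after the result was seen. Among the lists not described for every region, primary wall cellulose synthases took 0.027% ± 0.010, 0.050% ± 0.036 and 0.042% ± 0.013 of tension counts in Regions 1 to 3, against 0.014% ± 0.0046, 0.017% ± 0.025 and 0.012% ± 0.013 of normal counts (SD, n = 3), with no overlap in Region 3 alone (exact permutation p = 0.1, and 0.2 and 0.3 in Regions 1 and 2). Secondary wall transcription factors went the other way, from 0.068% ± 0.047, 0.061% ± 0.026 and 0.036% ± 0.024 in normal to 0.024% ± 0.0078, 0.025% ± 0.0092 and 0.013% ± 0.011 in tension wood (exact permutation p = 0.1, 0.1 and 0.3). Single libraries carried several of these means: without normal replicate 2, primary wall cellulose synthases took 0.0025% and 0.0051% in normal Regions 2 and 3, and transcription factors 0.041% and 0.023% in normal Regions 1 and 3. Without tension replicate 3 the primary wall list took 0.030% in tension Region 2, and without tension replicate 1 the transcription factors 0.0085% in tension Region 3. Accessory proteins of cellulose synthesis took 0.169% ± 0.015 of tension and 0.0095% ± 0.0082 of normal counts in Region 2, and 0.143% ± 0.040 and 0.020% ± 0.0044 in Region 3. These 3 lists rest on few counts, and the smallest p that 3 libraries against 3 allow is 0.1.

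The pattern that stands out is that normal and tension profiles were nearly unrelated, while at most 4 genes were called between regions of 1 wood. Those region tests recovered 16% to 41.4% of the simulated 2-fold changes in genes that passed the filter, or 8 to 24 of 100 changed genes. Depth alone did not account for the low correlation between the woods: at 5733 counts per library the lowest correlation within tension wood was 0.572 and the highest between the woods 0.135. A displacement of all row labels of the normal table against its counts is also argued against. The 49 listed wall genes in it held 2.53% of its counts, just above the highest of 10000 random sets of as many genes (median 0.674%, highest 2.52%). In the tension table the 55 listed genes held 8.56% (random median 0.540%, highest 3.88%). A displacement of part of the rows would not show in this test, so it stays open. Separate library preparation or sequencing of the wood types may contribute and cannot be told apart from the wood itself, because no source names a preparation and each table holds 1 wood (median correlation between the woods 0.097). The sources used here also do not say whether both tables were aligned and counted with the same settings, which cannot be told apart either. A response of the developing xylem to bending is the biological explanation that the design names, and it stays open as untested.

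For each comparison of 3 against 3, there are 10 splits of the libraries, too few for a share under 0.05. Between the woods, the real split gave 913, 704, 195 and 1746 calls in Regions 1 to 3 and summed, and the highest other split 0 in each. Every other split there put libraries of both woods in each group, so the difference between the woods entered the spread within groups. That held calls down whatever the source of the difference, so the 0 lends no support. In normal wood the real split gave 0, 0 and 1 calls (Region 2 against 1, 3 against 2, 3 against 1), and the highest other 1, 1 and 0; as many calls as the real split came from 10, 10 and 1 of the 10 splits. In tension wood it gave 2, 0 and 4, the highest other split gave 2, 2 and 2, and 2, 10 and 1 splits gave as many. Of the 4 splits that part every biological replicate's pair of regions, the highest other than the real one gave 0, 0 and 0 calls in normal and 1, 1 and 0 in tension wood; the remaining splits keep both regions of 1 replicate on the same side.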
